A study of Homo sapiens with 48 samples.

How the data were processed

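RNA was measured in DLD-1 cells, a human colorectal cancer line. The parental line carried TIR1, the plant receptor through which auxin directs proteins with an auxin-inducible degron (AID) to the proteasome. In the CNOT1-AID and CNOT4-AID lines the degron sat on CNOT1 or on CNOT4, so that auxin removes that protein. The steady-state set held 24 libraries in 12 groups of 2: the 3 lines, each untreated or with 1 mM auxin, at 8 h and 24 h. The triptolide set held 24 libraries in 12 groups of 2: the 3 lines after 0, 3, 6 and 12 h of 1 µM triptolide, which blocks the start of transcription, with auxin added 2 h before it. Per the labels, libraries were made from 500 ng of total RNA after removal of ribosomal RNA, with 2 µl of a 1 in 200 dilution of ERCC spike-in RNA. Sequencing of newly made RNA (TT-seq), which the labels mention, was not analysed here.

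The submitters' processing notes name STAR 2.5.1b, RSEM, DESeq2, SAMtools and featureCounts and the human build hg38 (GRCh38), without saying which tool made which table. The deposited steady-state values are TPM (transcript abundances corrected for gene length and scaled to a fixed total), given to 2 decimals, and every column was checked to sum to the same total within rounding (999998.92 to 1000000.81). The depth behind these TPM values is unknown. The deposited triptolide values are raw counts, whole numbers with 18216427 to 26723618 counts per library. All 58721 gene identifiers were found in GENCODE 29, which gave symbols, gene types and positions on GRCh38. Every column was mapped to a sample from the labels, and 0 columns were left over.

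Before the data were examined, the groups, comparisons, gene lists, alternatives and the rule for naming genes were fixed. That plan had taken the steady-state table for counts. Because it holds TPM, the steady-state fit was changed to limma 3.58.1 (trend, robust empirical Bayes) on log2 of TPM scaled with TMM (trimmed mean of M values) plus 0.5, and the planned DESeq2 alternative for this set was not run. Genes were tested where at least 2 libraries held 1 TPM or more, which left 14921 genes. The model gave each of the 12 groups its own mean, with 12 residual degrees of freedom and 16 contrasts: auxin against untreated in each line at each time, differences of these responses between lines and between times, and untreated tagged lines against the untreated parental line. TPM levels in the text are as deposited, before TMM scaling, so their ratios differ from the fitted folds.

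Triptolide counts were fitted with edgeR 4.0.16 (robust quasi-likelihood) for 16806 genes left by its expression filter. Slopes in log2 units per hour of triptolide were fitted per line, with library sizes scaled to the 56 of 92 ERCC sequences that had a mean of at least 10 counts, and compared in 3 contrasts with 18 residual degrees of freedom. A positive slope difference is slower loss of an mRNA, and a negative one is faster loss or, where the level rose in parental cells, a smaller rise or a fall. Half-lives of single genes came from the slopes of this fit. Half-lives beyond 12 h, the last time sampled, are extrapolated from slopes near 0. Medians of half-lives came from a second edgeR fit with a dispersion for each gene, over genes with at least 5 CPM (counts scaled to library size) that declined in all 3 lines, and that fit gave longer half-lives for several of the fastest mRNAs. Lines were also compared at 0 h with TMM scaling in 2 contrasts. Where a group held 0 counts, a fold is a lower bound against a floor of 3 counts over the group. Counting floors cover counting error only, since reads copied by PCR are not independent molecules.

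All p-values were adjusted with the Benjamini-Hochberg method within each contrast, with a threshold of 0.05. They measure the spread between these libraries, which may be technical, since how the libraries of a group were cultured is not stated. Errors are standard errors (SE) of the fit, or standard deviations (SD) for levels, and n = 2 libraries per group throughout. Altogether 27 gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. The preset test calls far more lists than the estimated one. The genes named are the 10 with the largest rise and the 10 with the largest fall per main comparison (5 and 5 for untreated lines and parental cells, 3 and 3 otherwise) among those past the threshold. They had a mean of at least 5 (TPM or CPM) and every auxin library beyond every untreated library, or for slopes the same sign in each replicate alone. Clone names, genes with MIR, SNOR, RNU, RN7 or RNA5 symbols and ERCC sequences were passed over. Genes named outside this rule are marked as chosen after their values were seen. All CCR4-NOT subunits are named, and up to 4 members of each list by the same rule. Expression of fixed marker genes for colon epithelium and other cell types was checked as well.

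Alternatives were median-of-ratios, ERCC or no scaling (steady state), and TMM or ribosomal protein scaling and DESeq2 1.42.0 (triptolide). Others were further filters, pseudocounts of 0.1 and 1, and a 2-fold cutoff on the fitted change on top of the p threshold. A fit of each comparison's own libraries, shorter time courses, and leaving out each library were also used. In the last case the lone library of a group is assumed to vary like the others.

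The fits were tested on simulated data. With 200 genes changed in the steady-state table, limma found 60% of genes moved by 0.5 on the log2 scale, 88% of those moved by 1 and 96% of those moved by 2, with 12 false calls. For slopes edgeR found 8% of genes moved by 0.1 per hour, 66% by 0.2 and 82% by 0.4, with 3 false calls. A simulated median half-life of 10.7 h was estimated as 10.5 h by the fit of the slope tests. The second fit, which gave the reported medians, was not run on simulated data. Every simulated line had parental slopes, apart from the genes changed in CNOT1-AID cells, so longer medians were not tested. The simulations of slopes and half-lives took the scaling factors as known and drew genes independently, so they do not test errors of the ERCC scaling. Other software was R 4.3.3, the R package data.table (version 1.17.8), Python 3.11.15 and matplotlib 3.10.9.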

Results

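RNA of 3 DLD-1 colorectal cancer lines was compared: the parental TIR1 line, and lines in which auxin removes CNOT1 or CNOT4. CNOT1 is the scaffold of the CCR4-NOT complex, which shortens the poly(A) tails of mRNAs, and CNOT4 is a ubiquitin ligase that binds it. The steady-state set (24 libraries, TPM, depth unknown) and the triptolide set (24 libraries, 18216427 to 26723618 counts each) each held 12 groups of 2 libraries. Protein-coding genes made up 30.6% of TPM in replicate 1 of CNOT4-AID cells with auxin at 8 h and 39.5% in replicate 2, and small nuclear RNAs made up 34.1% and 26.3%. In untreated CNOT4-AID cells at 8 h these shares were 38.05% and 37.82%, and 27.53% and 27.32%. Untreated parental cells at 8 h held 46.35% and 44.23%, and 17.54% and 19.31%, so the untreated lines differed in this as well. ERCC sequences took 2.25% and 3.92% of counts in the pair of CNOT4-AID libraries at 12 h of triptolide. The pair of parental libraries at 0 h of triptolide agreed least (r 0.9629 and SD of the log2 difference 0.875, against r of at least 0.9784 and SD of at most 0.728 in the other triptolide pairs), with chi-square per degree of freedom of 85.1 against 2.68 to 20. Parental slopes and 0 h differences rest on that pair. Of 15 markers of colon epithelium 10 had a mean of at least 1 TPM, against 1 of 7 markers of blood (CD14, 1 TPM) and 2 of 4 neural markers (TUBB3 at 73.8 TPM and MAP2 at 2.78 TPM). All 8 fibroblast and 4 endothelium markers had means below 1 TPM (at most 0.342 and 0.332 TPM), while COL1A1 reached 2.31 TPM and DCN 1.78 TPM in single libraries.

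The mRNA of the tagged genes was read first, since the degron acts on protein, which was not measured. In untreated cells at 8 h and 24 h, CNOT1 (chromosome 16, 58519951 to 58629886) stood at 86.1 ± 3.16 and 93.3 ± 2.64 TPM in parental cells (SD, n = 2). It stood at 54.9 ± 8.42 and 63.7 ± 6.62 TPM in CNOT1-AID cells, and at 73.1 ± 1.3 and 83.6 ± 1.68 TPM in CNOT4-AID cells. With auxin CNOT1 was at 97.9 ± 10.2 and 101 ± 2.14, at 46.6 ± 2.34 and 42.9 ± 4.26, and at 66.3 ± 13.4 and 89.3 ± 2.29 TPM in the same order. Untreated CNOT1-AID cells held 1.48 times less CNOT1 mRNA than parental cells (log2 -0.57 ± 0.048 SE, adjusted p = 3.07e-07). CNOT4 (chromosome 7, 135361795 to 135510127) was 1.29 times higher in untreated CNOT4-AID cells (log2 0.37 ± 0.060, adjusted p = 0.000386), which ended without scaling (0.11, adjusted p = 0.31). Its level in CNOT4-AID cells was 9.39 ± 0.523 TPM untreated and 9.72 ± 1.5 with auxin at 8 h, and 10.1 ± 0.184 and 12.5 ± 0.099 at 24 h, where neither change passed (adjusted p = 0.445 and 0.237). In parental cells CNOT4 lay between 8.46 ± 0.544 and 10 ± 0.46 TPM.

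Removal of CNOT1 raised the mRNAs of several partners in its own complex. At 8 h and 24 h CNOT4 rose 3.15-fold and 4.08-fold (log2 1.65 ± 0.084 and 2.03 ± 0.084), reaching 41.6 ± 3.96 TPM. The deadenylases CNOT6L (2.7-fold and 3.75-fold) and CNOT8 (2.3-fold and 3.28-fold), the complex-bound protein TNKS1BP1 (3.02-fold and 3.62-fold), and the scaffold partners CNOT2 (1.57-fold and 1.69-fold) and CNOT3 (1.54-fold and 1.6-fold) rose at each time. CNOT9, which binds CNOT1, did not pass at 8 h (log2 0.15, adjusted p = 0.0546) and rose at 24 h (0.36 ± 0.065). At 8 h it did pass without CNOT1-AID untreated replicate 1 (0.20), without auxin replicate 2 (0.22), and with ERCC scaling (0.63) or none (0.44). CNOT1 mRNA fell by 0.52 ± 0.068 and 0.82 ± 0.068 on the log2 scale, and the 8 h fall ended with ERCC scaling (-0.05) and with none (-0.23). CNOT7 fell by 0.29 and 0.43 and CNOT6 fell by 0.31 and 0.36; with ERCC scaling at 8 h they stood at 0.18 and 0.16, so their direction depended on the scaling. CNOT10 and CNOT11, which form a module of the complex, passed neither at 8 h (0.11 and 0.06) nor at 24 h (-0.01 and -0.03) with the main scaling, while ERCC scaling put them at 0.58 and 0.53, and at 0.34 and 0.32.

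At 8 h without CNOT1, the zinc finger gene ZNF296 (chromosome 19, 45071500 to 45076588) rose most among the named genes, 15.8-fold (log2 3.98 ± 0.087, adjusted p = 3.67e-15), from 5.36 ± 0.262 to 113 ± 4.87 TPM. IER5L rose 10.3-fold (63.1 ± 0.354 TPM with auxin), the MAP kinase phosphatase DUSP2 10.2-fold (5.7 ± 0.566 to 76.6 ± 3.71 TPM), FOSB, a partner of JUN, 9.76-fold, the G-protein regulator RGS16 8.9-fold, and TRIB1, which directs proteins to degradation, 8.77-fold. The cytoskeletal regulator CDC42EP2 (9.5-fold), the repressor of epithelial genes SNAI1 (8.82-fold) and TXNIP, an inhibitor of glucose uptake (8.56-fold, to 47.7 ± 0.707 TPM), also rose. SIK1B rose 10.1-fold, though its reads may be shared with its near-identical copy SIK1. In the other direction NANOS1, an RNA-binding protein that recruits this complex, fell from 16 ± 0.361 to 1.82 ± 0.403 TPM (log2 -3.07 ± 0.11). WSB2, a substrate adaptor of ubiquitin ligases, fell from 75.4 ± 3.31 to 11.2 ± 0.12 TPM (-2.98 ± 0.044), and the translation repressor EIF4EBP2 fell from 33.9 ± 1.41 to 5.86 ± 0.0919 TPM (-2.71 ± 0.049). The chemokine CXCL5 (-2.70), the phosphatase inhibitor PPP1R14B (-2.51), the phosphatase-like CTDSPL (-2.37), CCDC3 (-2.38), KLHL5 (-2.35) and the membrane protein MAL2 (-2.33) fell as well. The small RNA locus RF02124 was listed at 0 in both auxin libraries and at 15.5 ± 7.06 TPM in untreated ones (adjusted p = 0.0475), a call that ended without scaling and without any 1 of its 4 libraries (adjusted p = 0.0842 to 0.166). In all limma called 9374 of 14921 genes, 4933 higher and 4441 lower, and 1385 rose and 774 fell at least 2-fold. The median of all genes moved by 0.42 with ERCC scaling (7818 higher, 1424 lower) and by 0.26 without scaling (6624 higher, 2251 lower), so directions below are relative to the median gene.

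Zinc finger genes rose as a list at 8 h: of 350 measured, 283 rose and 11 fell (284 and 12 adjusted over the list alone), with a median log2 of 1.04. Most code for DNA-binding repressors, and ZNF416 (7.39-fold), ZNF57 (7.12-fold) and ZNF574 (7.01-fold) led them. Their set test passed with camera (adjusted p = 4.54e-23) and passed with an estimated correlation (0.000361), the only list at 8 h to do so. Of 51 immediate early genes 32 rose and 10 fell (32 and 10 adjusted over the list alone; adjusted p = 0.195 with an estimated correlation), among them JUNB (5.77-fold), while ATF3 fell by 1.25 and PPP1R15A, which restarts translation after stress, fell by 1.57. NFKBIA, the inhibitor of NF-kB, rose 5.99-fold (27.4 ± 0.728 to 205 ± 10.2 TPM) and TNFAIP2 3.8-fold. Of 24 p53 targets 16 rose (16 adjusted over the list alone), with GDF15 4.87-fold and PLK3 4.09-fold higher (adjusted p = 0.144 with an estimated correlation). Of 19 heat shock genes 16 rose (17 adjusted over the list alone), with HSPA6 3.4-fold and HSPA8 1.73-fold higher (0.144 with an estimated correlation). The antiproliferative adaptors of deadenylation BTG2 (4.61-fold) and TOB2 (3.11-fold) and the decay factor ZFP36L2 (2.64-fold) rose, and LSM4, a decapping factor, fell by 1.46. The elongation factors ELL (3.6-fold), HEXIM1 (2.94-fold) and CCNT1 (2.85-fold) rose, as did the ribosome rescue factor PELO (2.88-fold) and the nonsense-mediated decay factor SMG8 (2.95-fold). The Wnt targets AXIN2 (3.38-fold) and SOX9 (2.58-fold), the cell death genes BCL2L11 (5.78-fold) and BMF (3.08-fold), and the nuclear RNA NEAT1 (2.66-fold) rose. In their lists 18 rose and 12 fell of 45 deadenylation and decapping factors, 18 and 7 of 33 for RNA polymerase II and elongation, 12 and 6 of 27 for ribosome quality control, and 16 and 5 of 27 for nonsense-mediated decay. The same counts were 12 and 6 of 20 NF-kB targets, 9 and 3 of 17 Wnt targets, 9 and 6 of 23 apoptosis regulators, and 3 and 8 of 11 abundant non-coding RNAs (median -0.42; 4 and 0 with ERCC scaling). With an estimated correlation none of these 8 lists passed (adjusted p = 0.144 to 0.495).

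Abundant mRNAs for translation and respiration moved down at 8 h relative to the median gene. Of 78 ribosomal protein genes 75 fell (76 adjusted over the list alone; adjusted p = 0.209 with an estimated correlation), with RPSA at -1.13 ± 0.060, RPS12 at -0.96 and RPLP0 at -0.93 on the log2 scale. With ERCC scaling 5 rose and 4 fell, so that this direction held only relative to other genes. Of 72 nuclear genes for oxidative phosphorylation 59 fell (59 adjusted over the list alone; 23 rose and 9 fell with ERCC scaling; adjusted p = 0.183 with an estimated correlation), with COX8A at -1.03 ± 0.062. Of 32 proteasome genes 24 fell (24 adjusted over the list alone), among them PSMB1 at -0.58 and PSMA7 at -0.58, and with ERCC scaling 17 rose (0.209 with an estimated correlation). Of 21 long-lived housekeeping mRNAs 16 fell, including FTH1 (ferritin) at -1.38 and B2M at -0.84 (0.382 with an estimated correlation). With ERCC scaling 7 of the 21 rose and 2 fell. In the cell cycle lists E2F1 fell by 1.66, CCNE2 rose 2.01-fold, and the mitotic genes HJURP (2.46-fold) and UBE2C (2.14-fold) rose. Replication-dependent histones split, with 10 higher and 21 lower (28 and 1 with ERCC scaling) and a median of -0.15 against a mean of 0.05; HIST1H2BG rose 5.29-fold, and histone reads may be shared between copies.

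**Figure D1:**
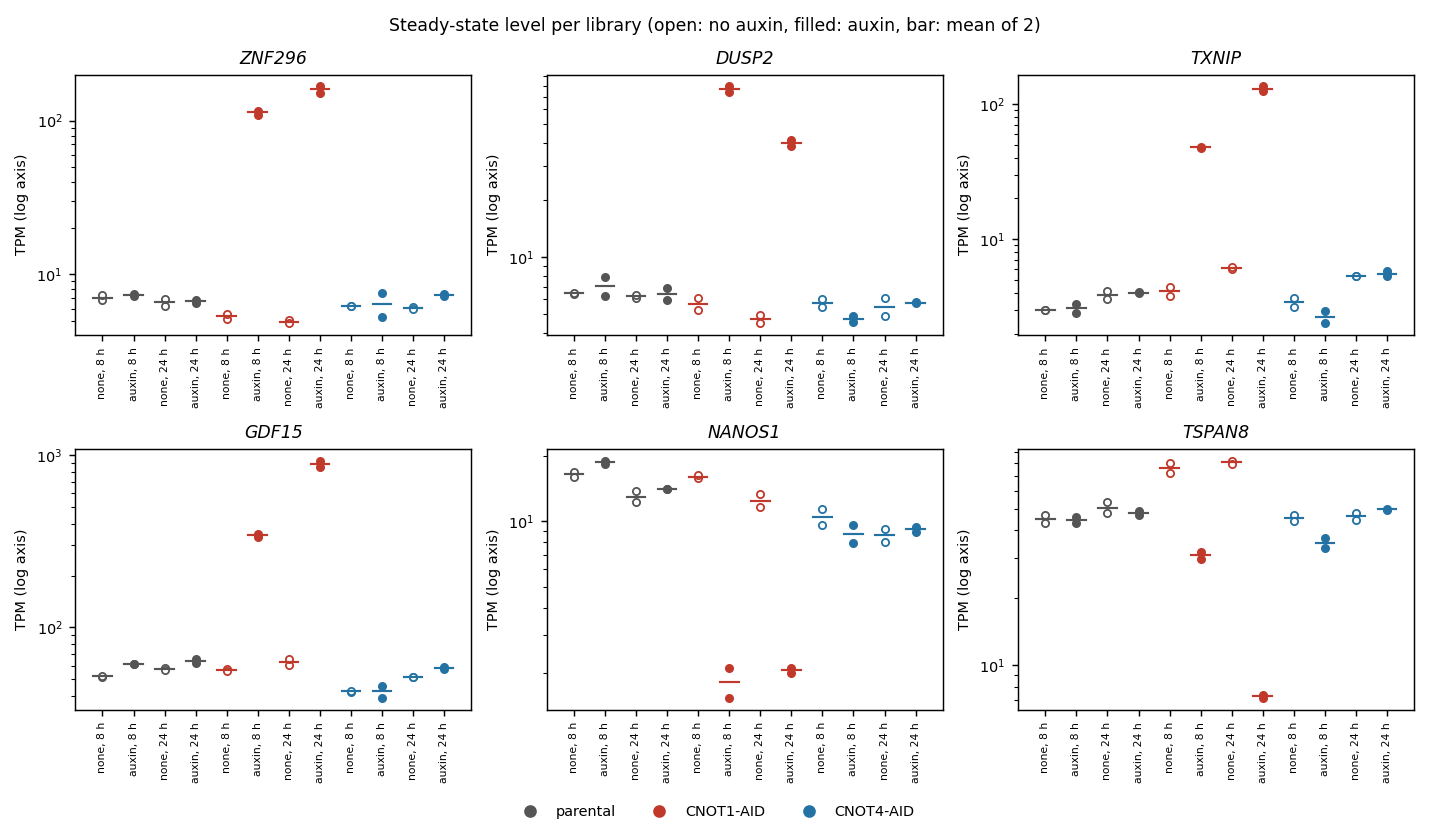
Steady-state TPM (log axis) of 6 genes in each of the 24 libraries, by line, auxin and time (open points untreated, filled points auxin, bars the mean of 2). ZNF296 stood at 113 and 160 TPM in CNOT1-AID cells with auxin at 8 h and 24 h, and no other group's mean passed 7.36 TPM.

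After 24 h without CNOT1 the changes were larger. ZNF296 rose 24.4-fold (log2 4.61 ± 0.087, to 160 ± 11 TPM), TXNIP 16.4-fold (129 ± 7.93 TPM), CDC42EP2 15.8-fold and the receptor GPRC5C 14.4-fold (1.57 ± 0.311 to 35.4 ± 0.346 TPM). The red cell antigen gene SMIM1 rose 14.1-fold (to 10.5 ± 0.686 TPM), INKA1 12.7-fold, the stress kinase MAP3K12 12.4-fold and RGS14 11.3-fold. GDF15, a stress hormone, rose 11.6-fold from 63.1 ± 3.25 to 885 ± 51 TPM. TSPAN8, a tetraspanin of gut epithelium (chromosome 12), fell from 80.6 ± 1.53 to 7.24 ± 0.12 TPM (-3.63 ± 0.064), and CXCL5 from 63.2 ± 2.68 to 5.72 ± 0.0212 TPM (-3.59 ± 0.053). CMTM6 (-3.44), which stabilises PD-L1 at the cell surface, the palmitoyltransferase ZDHHC2 (-3.24), the matrix protein TNC (-3.19) and PPP1R14B (-3.16) fell as well. LUZP6 (-3.65) lies inside MTPN and may share its reads, and its call ended without auxin replicate 1 (-2.18, adjusted p = 0.052). The small RNAs SCARNA14 (listed at 0 untreated, 12.8 ± 1.96 TPM with auxin), SCARNA20 and RF00100 lost their calls without single libraries. Adjusted p was 0.0521 without auxin replicate 2 for SCARNA14. For SCARNA20 it was 0.108 without untreated replicate 2, 0.0577 without auxin replicate 1 and 0.0574 without auxin replicate 2. For RF00100 it was 0.0527 to 0.122 without each of the 4 libraries. The small RNA RF00322 (-5.04, adjusted p = 0.000635) kept its call without each of them. Of the cell type markers with a mean of at least 1 TPM, CLDN4 (1.54), CDX2 (0.32), KRT19 (0.18), TUBB3 (0.74) and CD14 (1.73) rose. EPCAM (-0.56), KRT8 (-1.51), KRT18 (-1.19), KRT20 (-1.47), CDH1 (-0.93), CDH17 (-1.81) and MAP2 (-1.78) fell, and CLDN3 did not pass (-0.23, adjusted p = 0.188). COL1A1, with a mean of 0.342 TPM, rose as well (1.75). Altogether 10670 genes passed, 5472 higher and 5198 lower, with 2210 up and 1638 down at least 2-fold. ERCC scaling moved the median gene by 0.29 (6858 higher, 2961 lower), and no scaling by 0.21 (6546 higher, 3564 lower).

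Lists at 24 h included 3 that passed with an estimated correlation in camera. Zinc finger genes kept the rise (258 higher, 30 lower of 350; 259 and 30 adjusted over the list alone; adjusted p = 0.00865 with an estimated correlation), with ZNF574 9.11-fold, ZNF416 6.59-fold and ZNF408 6.07-fold higher. Hypoxia genes rose, 13 of 18 against 1 lower (13 and 1 adjusted over the list alone; 0.0303), through the demethylase KDM3A (3.93-fold), NDRG1 (3.87-fold), the glycolytic regulator PFKFB3 (3.07-fold) and EGLN3 (3.03-fold). Cholesterol synthesis genes fell, 19 of 25 against 4 higher (19 and 4 adjusted over the list alone; 0.0309), including their regulator SREBF2 (-2.44 ± 0.085), the sterol carrier STARD4 (-1.65) and the enzymes MVK (-1.58) and MVD (-1.52); with ERCC scaling 12 fell and 5 rose. Of 19 heat shock genes 16 rose (16 adjusted over the list alone; adjusted p = 0.0543 with an estimated correlation), with HSPA6 9-fold, DNAJB1 2.96-fold and BAG3 2.56-fold higher, and HSPA1B 3.6-fold higher although its reads may be shared with HSPA1A. Among immediate early genes (34 higher, 13 lower; 34 and 14 adjusted over the list alone; 0.247 with an estimated correlation) TRIB1 rose 10.8-fold, the vascular factor KLF2 8.56-fold and the cytokine brake SOCS3 7.16-fold, and ID1 fell from 56.9 ± 1.94 to 8.62 ± 0.276 TPM (-2.90). NF-kB targets TNFAIP2 (9.2-fold) and PLAUR (5.26-fold) rose (12 of 20; 0.118 with an estimated correlation), as did the p53 targets PLK3 (6.88-fold) and BBC3 (4.59-fold; 15 of 24; 0.149 with an estimated correlation). Of 24 interferon-stimulated genes 16 rose, with UBE2L6 3.96-fold and IRF9 2.94-fold higher (0.106 with an estimated correlation).

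The direction of the cell cycle lists at 24 h depended on the scaling. Of 53 G2/M genes 30 fell and 15 rose (31 and 15 adjusted over the list alone; 10 and 20 with ERCC scaling; adjusted p = 0.308 with an estimated correlation). The survivin gene BIRC5 fell from 66.5 ± 0.919 to 12.4 ± 0.148 TPM (-2.63), CBX5 by 2.08 and the proliferation marker MKI67 by 1.40. Of 45 G1/S genes 25 fell and 10 rose (12 and 20 with ERCC scaling; 0.293 with an estimated correlation), with E2F1 at -1.66, TYMS at -1.43 and POLA1 at -1.35. Of 17 Wnt targets 7 rose and 8 fell (7 and 5 with ERCC scaling; 0.821 with an estimated correlation), with ASCL2 (-1.75) and LGR5 (-1.60) lower and AXIN2 (3.07-fold) and EPHB3 (3.3-fold) higher. ANKRD1 (-3.34), a YAP target, and NT5E (-2.43) fell within a list with 7 higher, 7 lower, a median of 0.15 and a mean of -0.19. Of 27 nonsense-mediated decay factors and reporters 16 fell and 2 rose (16 and 2 adjusted over the list alone; 8 and 7 with ERCC scaling; 0.0541 with an estimated correlation), SMG5 and the amino acid transporter SLC7A5 at -1.26 and -2.01, against SMG8 5.23-fold higher. Ribosomal protein genes had 58 lower and 1 higher (10 and 19 with ERCC scaling; 0.405 with an estimated correlation) and oxidative phosphorylation genes 50 lower and 13 higher (20 and 22 with ERCC scaling; 0.308 with an estimated correlation), with ATP5MC2 at -1.46. FTH1 fell from 1590 ± 22.4 to 405 ± 14.3 TPM while FTL, the other ferritin chain, rose 1.93-fold. DDIT4, an inhibitor of mTOR, rose 10.1-fold, the stress factor DDIT3 3.62-fold, and CHAC1 2.78-fold in a stress response list that went both ways (12 higher, 16 lower). BTG1 (4.13-fold), BTG2 (6.26-fold) and ZFP36L2 (4.46-fold) rose and LSM4 fell by 2.15.

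**Figure D2:**
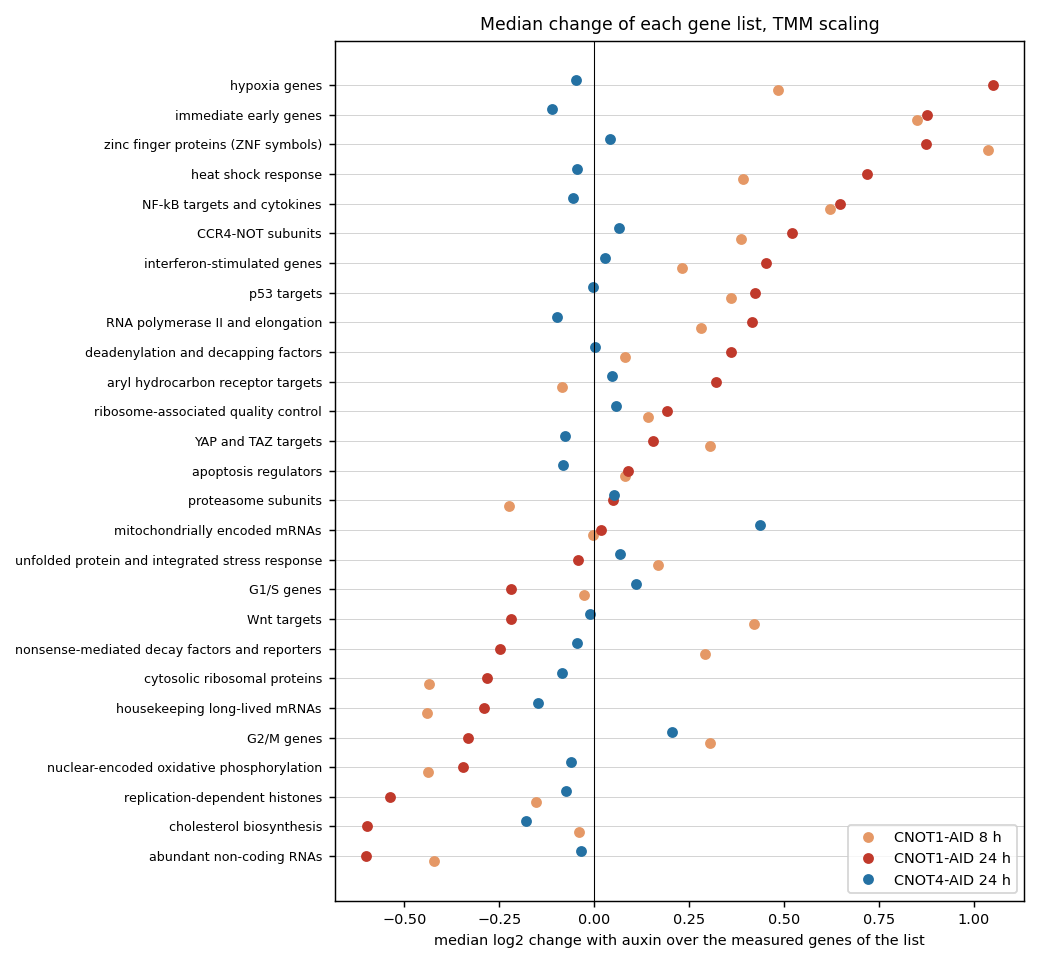
Median log2 change with auxin (TMM scaling) over the measured genes of each of 27 lists, 1 point per comparison. In CNOT1-AID cells zinc finger genes lay at 1.04 and 0.87 at 8 h and 24 h and ribosomal protein genes at -0.44 and -0.28; the latter lay at 0.04 and 0.08 with ERCC scaling.

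Responses were next set against those of parental cells, which separates loss of CNOT1 from auxin itself. ZNF296 rose 16.2-fold more than in parental cells at 8 h and 24-fold more at 24 h, IER5L 10.1-fold and DUSP2 10-fold more at 8 h, and CDC42EP2 17.4-fold and TXNIP 15.8-fold more at 24 h. NANOS1 (-3.15 ± 0.16) and WSB2 (-2.91 ± 0.063) responded lower at 8 h and TSPAN8 (-3.56 ± 0.090) and RF00322 (-6.59) at 24 h. SCARNA20 (-7.70, adjusted p = 0.014) lost this call without parental auxin replicate 2 (adjusted p = 0.0668) or CNOT1-AID untreated replicate 2 (0.0531). The difference passed for 7504 genes at 8 h (4035 higher, 3469 lower; 6914 and 828 with ERCC scaling, 4671 and 1881 with none) and 9237 at 24 h (4823 and 4414; 6016 and 2144 with ERCC scaling, 5812 and 2771 with none). ERCC scaling moved the medians by 0.47 and 0.32, and no scaling by 0.17 and 0.23. Between 8 h and 24 h without CNOT1, IER3, an early response gene, rose 4.14-fold further (2.05 ± 0.087), the immunoproteasome gene PSMB9 4.06-fold and GPRC5C 3.94-fold, and ASCL2 fell by 2.69 ± 0.18. RF00322 (-5.64) fell too, and RNVU1-3 (-2.75) lost its call without any 1 replicate 2 library (adjusted p = 0.0818 to 0.116). In all 5422 genes differed between times (2602 higher, 2820 lower; 989 and 2317 with ERCC scaling, median -0.11).

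Auxin in CNOT4-AID cells changed far fewer genes. At 8 h CYP1A1, which the aryl hydrocarbon receptor induces, rose 2.25-fold (1.17 ± 0.14, adjusted p = 0.00161) from 2.46 ± 0.0495 to 5.44 ± 0.262 TPM, and it went from 2.42 ± 0.205 to 5.08 ± 0.219 TPM in parental cells with auxin. CYR61, a YAP target, fell from 84.4 ± 3.81 to 51.8 ± 2.73 TPM (-0.55 ± 0.064), and it fell in parental cells too. Smaller rises were those of CMC1 (1.47-fold), the ribosome assembly factors UTP14A (1.41-fold) and RIOK2 (1.44-fold), MRPS31 (1.41-fold), the RNA polymerase III subunit POLR3C (1.39-fold) and the melanosome adaptor MLPH (1.34-fold). MAPK1IP1L (1.35-fold), MACO1 (1.34-fold), YJU2 (1.32-fold) and GPKOW (1.31-fold) rose too. The complex subunit CNOT10 rose 1.27-fold, AGO2 1.24-fold, the replication factor DTL 1.26-fold, and the mitotic genes CDC20 1.27-fold and TPX2 1.18-fold. CEMIP2 (-0.42), DNAJB1 (-0.30), HSPA6 (-0.66), C16orf70 (-0.27), SNHG12 (-0.26) and HSPA1B (-0.30, shared reads possible) fell. Only CYR61 and CYP1A1 among these passed without each 1 of the 4 libraries, and they also passed with ERCC scaling, where 5 genes passed (3 higher, 2 lower; 3 and 8 with no scaling, median -0.13). YAP and TAZ targets were the 1 list that passed with an estimated correlation (adjusted p = 0.0083, median -0.10; 1 of 18 fell, 3 adjusted over the list alone). The 13 mitochondrial mRNAs had a median of 0.42 (adjusted p = 0.426 with an estimated correlation; 2 rose adjusted over the list alone). In all 43 genes passed (36 higher, 7 lower; 1596 at unadjusted p under 0.05), 107 without auxin replicate 1, 10 without auxin replicate 2, 6 without untreated replicate 1 and 10 without untreated replicate 2.

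At 24 h of auxin in CNOT4-AID cells, genes of cell division rose and cholesterol genes fell. NDC80, which ties chromosomes to spindle fibres, rose 1.57-fold (0.65 ± 0.093, from 9.22 ± 0.488 to 16.1 ± 0.622 TPM), and the mitotic genes DEPDC1 (1.59-fold), HMMR (1.5-fold), DLGAP5 (1.43-fold) and KIF11 (1.36-fold) and the replication genes FAM111B (1.64-fold), TIPIN (1.32-fold), CASP8AP2 (1.36-fold) and DTL (1.24-fold) rose. Of 53 G2/M genes 10 rose (24 higher and 2 lower adjusted over the list alone; 25 with ERCC scaling; adjusted p = 0.0216 with an estimated correlation), and 3 of 45 G1/S genes (7 and 1 adjusted over the list alone; 0.0788). The sterol enzymes DHCR7 (-0.41 ± 0.053, 65.7 ± 3.46 to 53.7 ± 2.21 TPM), EBP (-0.38) and MVK (-0.28) fell among 5 of 25 (13 adjusted over the list alone; 0.0142 with an estimated correlation); with ERCC scaling 2 of the 25 rose and the calls of these genes ended. Other rises were the zinc finger genes ZNF260 (1.74-fold), ZNF480 (1.72-fold) and ZNF678 (1.56-fold), the nuclear pore gene TPR (1.72-fold), SMIM19 (1.65-fold, 6.38 ± 0.247 to 11.8 ± 1 TPM), UACA (1.64-fold), MRPL1 (1.58-fold) and CDRT1 (1.58-fold). Rises were also seen for the cystine carrier SLC7A11 (1.5-fold), ASNS (1.24-fold), CEBPG (1.3-fold), CYP1A1 (1.69-fold), CYP1B1 (1.5-fold), PSMD14 (1.24-fold), CNOT10 (1.26-fold) and the mitochondrial MT-ND4L (1.32-fold).

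Among the named genes lower in CNOT4-AID cells at 24 h were CORO1A (-0.60), PDLIM2 (-0.60), the collagen receptor DDR1 (-0.57), the integrin ITGA5 (-0.53), PRADC1 (-0.59) and CRYBG2 (-0.58). So were the early response genes CSRNP1 (-0.52), IER3 (-0.41), ID1 (-0.39) and CYR61 (-0.28), the cell cycle inhibitor CDKN1A (-0.45), HSP90AB1 (-0.27) and RPSA (-0.33). EEF1A2 (-0.53) and the pseudogene PSMC1P5 (-1.28) may share reads with relatives, and RNVU1-6 (-0.80) is a variant U1 RNA. With ERCC scaling, which moved the median gene by 0.24, the calls of these genes ended except for CRYBG2 and PSMC1P5. NDC80, CEBPG, HSP90AB1 and DHCR7 were the named genes that passed without each 1 of the 4 libraries. The total was 673 genes (312 higher, 361 lower; 3350 at unadjusted p under 0.05; 1738 and 4 with ERCC scaling, 289 and 449 with median of ratios, 19 and 2 with none, where the median moved by 0.11). It was 21 without untreated replicate 1, 50 without auxin replicate 1 and 48 without auxin replicate 2. Against the parental response 10 genes passed at 24 h: SMIM19 (0.92 ± 0.16), the ribosome factor UTP23 (0.78 ± 0.12), the methyltransferase METTL5 (0.62 ± 0.095), DHCR7 (-0.52 ± 0.075), TM4SF1 (-0.51), and S100A16 (-0.48). The other 4, chosen after their values were seen, were NACA (0.59), PLRG1 (0.42), LRP10 (-0.43) and MIR320B2 (0.45 TPM on average). The count was 1 without untreated replicate 1 or either auxin library of either line, 23 without parental untreated replicate 2 and 46 without CNOT4-AID untreated replicate 2, and ERCC scaling left 1 gene.

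In parental cells auxin alone changed little. At 8 h limma called 3 genes (835 at unadjusted p under 0.05): CYR61 fell from 76.1 ± 6.28 to 60 ± 0.82 TPM (-0.44 ± 0.064, adjusted p = 0.0275). ANGPTL4, a lipase inhibitor chosen after its values were seen, rose (1.17 ± 0.18, adjusted p = 0.0408). The Y RNA locus RF00019 (chromosome 4) was at 29.7 ± 9.25 TPM in the auxin group and listed at 0 in the other groups. CYR61 lost its call without any 1 of the 4 libraries (adjusted p = 0.117 to 0.36), and 1 gene passed without untreated replicate 1, untreated replicate 2 or auxin replicate 1. At 24 h limma called 0 genes (755 at unadjusted p under 0.05), 1 without untreated replicate 1 and 5 without untreated replicate 2. The nonsense-mediated decay list passed camera at 24 h with an estimated correlation (adjusted p = 0.0134, median -0.06). Against the parental response at 8 h, CNOT4-AID cells differed at 2 loci, both called RF00019, 1 of them the locus above and the other chosen after its values were seen. The count was 10 without CNOT4-AID auxin replicate 1 and 4 without CNOT4-AID untreated replicate 2 or either parental untreated library. Between 24 h and 8 h in CNOT4-AID cells 3 loci differed: the glycosyltransferase B3GNT3 (-0.62 ± 0.093), and MIR320B2 and RF00019, chosen after their values were seen. B3GNT3 lost its call without any 1 of 8 libraries (adjusted p = 0.0609 to 0.2). Without CNOT4-AID auxin 8 h replicate 2 the count was 9.

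CNOT1 and CNOT4 removal were compared directly. ZNF296 responded 14.1-fold and 22.1-fold higher in CNOT1-AID than in CNOT4-AID cells at 8 h and 24 h, IER5L 11.1-fold and DUSP2 11-fold higher at 8 h, GPRC5C 18.5-fold and TXNIP 17-fold higher at 24 h. NANOS1 (-2.97 ± 0.16) and WSB2 (-2.88 ± 0.063) responded lower at 8 h, and TSPAN8 (-3.61 ± 0.090) and CXCL5 (-3.52 ± 0.076) at 24 h. RF02124 (-9.74) at 8 h and RF00322 (-4.20) at 24 h also passed. RF00322 lost its call without CNOT1-AID untreated or auxin replicate 1 (adjusted p = 0.075 and 0.0982) or CNOT4-AID untreated replicate 2 (0.0836) or auxin replicate 1 (0.0539). The difference passed for 7704 genes at 8 h (4120 higher, 3584 lower; 7085 and 798 with ERCC scaling, 6554 and 1099 with none; medians moved by 0.49 and 0.39) and 9278 at 24 h (4781 and 4497). Across 14921 genes, which are not independent replicates, the 2 responses had Pearson's r of -0.02 at 8 h and 0.04 at 24 h. Of the genes called at 24 h, 162 rose in both lines (114.4 by chance), 174 fell in both (125.8 by chance), 134 rose without CNOT1 and fell without CNOT4 (132.4) and 92 did the opposite (108.7).

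Untreated tagged lines already differed from parental cells. The chromosome 19 zinc finger genes ZNF540 (20.1 ± 0.346 TPM in parental cells at 8 h, against 0.165 ± 0.12 in CNOT1-AID and 0.245 ± 0.0778 in CNOT4-AID cells), HKR1 (16.6 ± 0.983 against 0.52 ± 0.283 and 1.27 ± 0.141 TPM), ZFP30 (-3.75 and -3.52), ZNF571 (-3.53 and -3.61), ZNF527 (-2.70 and -2.37) and ZNF607 (-2.35 and -2.67) were lower in both lines. The calcium-binding genes S100P (2.55-fold and 4.49-fold; 37 ± 3.51 TPM in parental cells at 8 h) and S100A4 (2.41-fold and 2.67-fold) were higher in both. The chloride channel CLIC5 (2.8-fold), TMEM139 (2.49-fold) and ADGRF1 (2.46-fold) were higher in CNOT1-AID cells. The adhesion receptor CD44 (3.23-fold), GGT1 (2.5-fold) and the pseudogene RPL23AP2 (4.08-fold, shared reads possible) were higher in CNOT4-AID cells. Of the other subunits, TNKS1BP1 (-0.28) was lower and CNOT8 (0.14) higher in CNOT1-AID, and CNOT6 (-0.16) lower in CNOT4-AID cells. CNOT8 and CNOT6 lost their calls with ERCC scaling and without several single libraries (adjusted p up to 0.0713 for CNOT8, without parental untreated 24 h replicate 1, and up to 0.136 for CNOT6, without parental untreated 8 h replicate 1). In all 3095 genes differed in CNOT1-AID (1511 higher, 1584 lower; 417 and 839 with ERCC scaling) and 3017 in CNOT4-AID cells (1563 and 1454; 1375 and 496 with ERCC scaling, 285 and 8397 with none, where the median moved by -0.25). The latter count was 1903 without parental 24 h replicate 1 and 1972 without CNOT4-AID 8 h replicate 2. Of these genes 616 were lower in both and 610 higher in both, with 40 and 65 in opposite directions, but both differences subtract the same 4 parental libraries, which adds to such counts. Across 14921 genes, which are not independent replicates, the 2 differences had r of 0.594, against 0.528 in simulated data with no effect. Differences with no library in common (1 line at 8 h, the other at 24 h) had r of 0.333 and 0.296. At 0 h of triptolide the pattern was deeper in counts: ZNF493 held 0 and 0 counts in CNOT1-AID cells against 344 and 681 in parental cells (at least 339-fold lower against the floor). ZNF570 was at least 330-fold lower in CNOT1-AID and 346-fold lower in CNOT4-AID cells, where ZNF793 and ZNF845 were at least 350-fold and 196-fold lower. ZNF431 held 1 and 0 counts in CNOT1-AID cells against 897 and 1783.

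**Figure D3:**
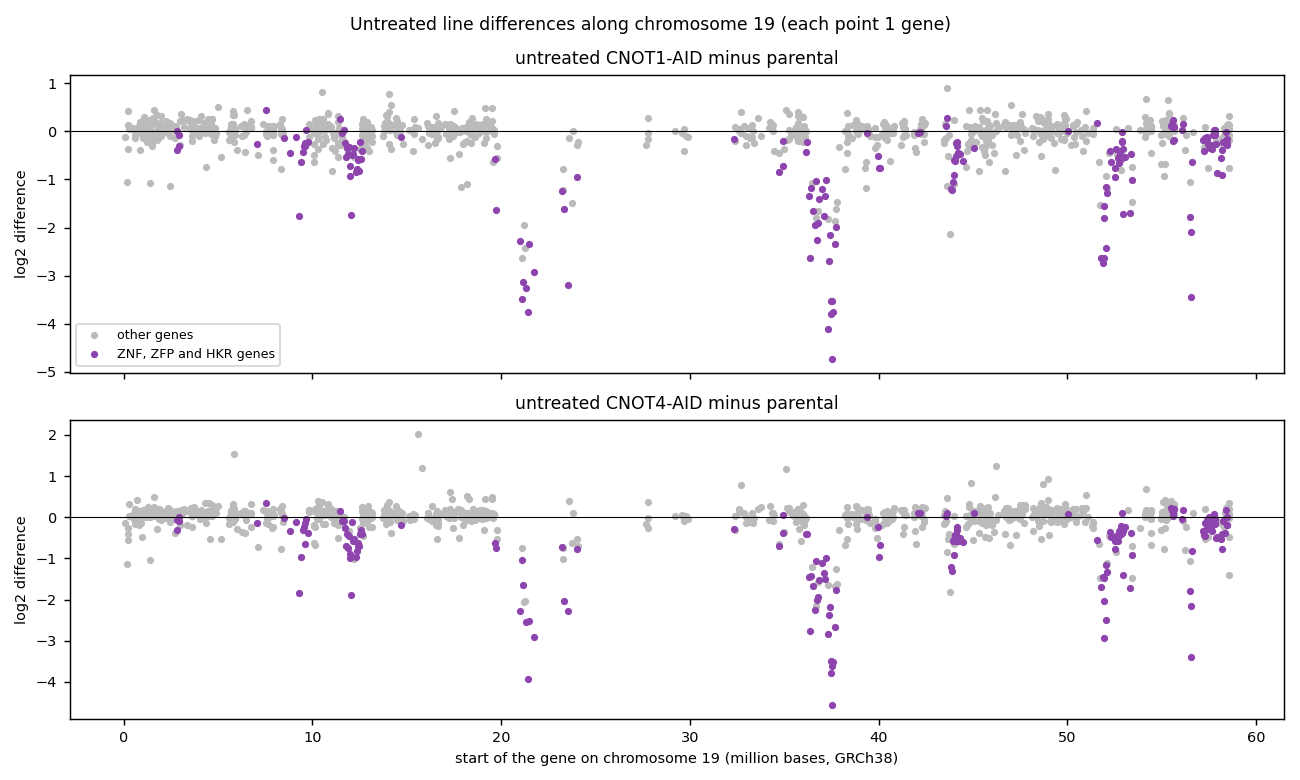
Log2 difference of untreated CNOT1-AID (top) and CNOT4-AID (bottom) from parental cells for each tested gene of chromosome 19, by start position (GRCh38); purple points are zinc finger genes with ZNF, ZFP or HKR symbols. Of 176 such genes 53 were at least 2-fold lower in CNOT1-AID cells and 48 in both lines.

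Other genes at 0 h of triptolide, after 2 h of auxin, separated the lines as well. All libraries of this set had auxin, so line and removal of the tagged protein cannot be told apart. NFIA, a transcription factor, was 11.6-fold higher in CNOT1-AID (495 and 415 counts against 37 and 42) and 12.5-fold higher in CNOT4-AID cells, the secreted glycoprotein LGALS3BP 9.39-fold higher in CNOT1-AID cells, and BAHCC1, a chromatin protein, 25.2-fold higher in CNOT4-AID cells. The pseudogene DUXAP10 held 163 and 206 counts in CNOT4-AID cells against 0 and 2, and the U1 locus RF00003 was 8.31-fold higher in CNOT1-AID cells (738 against 88.8 CPM). In all edgeR called 2436 genes in CNOT1-AID cells, 1622 higher and 814 lower. With ERCC scaling these were 1133 and 167 (median moved by 0.42), and with only the libraries compared 38 and 53. It called 2012 in CNOT4-AID cells, 1324 higher and 688 lower. With ERCC scaling these were 480 and 176 (median moved by 0.32), with ribosomal protein scaling 722 and 789, and with only the libraries compared 40 and 69. The first count was 4850 and 6439 without parental replicate 1 and 2 and 1156 and 1180 without CNOT1-AID replicate 1 and 2; the second was 4800 and 6153 without parental replicate 1 and 2.

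Blocking transcription showed how long existing mRNAs lasted in CNOT1-AID cells with auxin. Every triptolide library had auxin, so removal of the tagged protein and a difference of the line cannot be told apart in slopes and half-lives. For these values, here and below, "without CNOT1" and "without CNOT4" name the tagged lines with auxin. In parental cells KLF2, an early response factor, had a half-life of 1.16 h and 0.669% of its 0 h level left at 12 h, against 32.3 h and 79.1% without CNOT1 (slope difference 0.83 ± 0.14 log2 per hour, adjusted p = 0.000206). NFKBIA went from 1.4 h to 40.1 h (0.728% and 82.1% left at 12 h, slope difference 0.69 ± 0.15). The oncogene MYC, chosen after its values were seen, went from 1.77 h to 24.6 h (0.52 ± 0.13, adjusted p = 0.00745). In parental cells the fitted half-lives of KLF2 and NFKBIA are shorter than their shares left at 12 h imply. Slope differences of such fast mRNAs may therefore be too large. ZNF230 (0.85 ± 0.11, half-life 1.15 h to 84.9 h), RGS16 (0.85 ± 0.19), the TGF-beta decoy receptor BAMBI (0.80 ± 0.11), DUSP2 (0.74), DUSP1 (0.74), CSRNP1 (0.71), RNF39 (0.70) and CHAC1 (0.69) showed the largest slowing by the naming rule. The slope difference passed for 2935 of 16806 genes, 2767 slower and 168 faster (4135 at unadjusted p under 0.05); with TMM scaling it was 3446 slower and 2645 faster, and with ribosomal protein scaling 7790 and 199. Of 11 abundant non-coding RNAs 5 had lower slopes (5 adjusted over the list alone; adjusted p = 0.313 with an estimated correlation). Lower slopes than in parental cells were those of a pair of U1 loci named RF00003 (-0.40 and -0.39), RNVU1-18 (-0.34), RNVU1-7 (-0.32), the Y RNA RNY1 (-0.37), RMRP (-0.31), SCARNA16 (-0.29) and SCARNA7 (-0.25). So were those of the histone gene HIST1H4C (-0.14), TERC (-0.18) and NEAT1 (-0.12), and the pseudogenes RPL14P1 (-0.23) and YBX1P1 (-0.19), whose reads may come from relatives. Among these only HIST1H4C (slope -0.223) and NEAT1 (-0.143) declined in parental cells, where the others rose after triptolide (slopes of 0.226 and 0.153 for RF00003, 0.153 for RNVU1-18, 0.182 for RNVU1-7, 0.097 for RNY1, 0.206 for RMRP, 0.117 for SCARNA16, 0.141 for SCARNA7, 0.122 for TERC, 0.163 for RPL14P1 and 0.139 for YBX1P1). TERC and NEAT1 lost their calls without either parental 0 h library (adjusted p = 0.0628 to 0.0725) or without CNOT1-AID 12 h replicate 2 (0.057 and 0.0744), and NEAT1 without parental 12 h replicate 1 (0.0797).

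**Figure D4:**
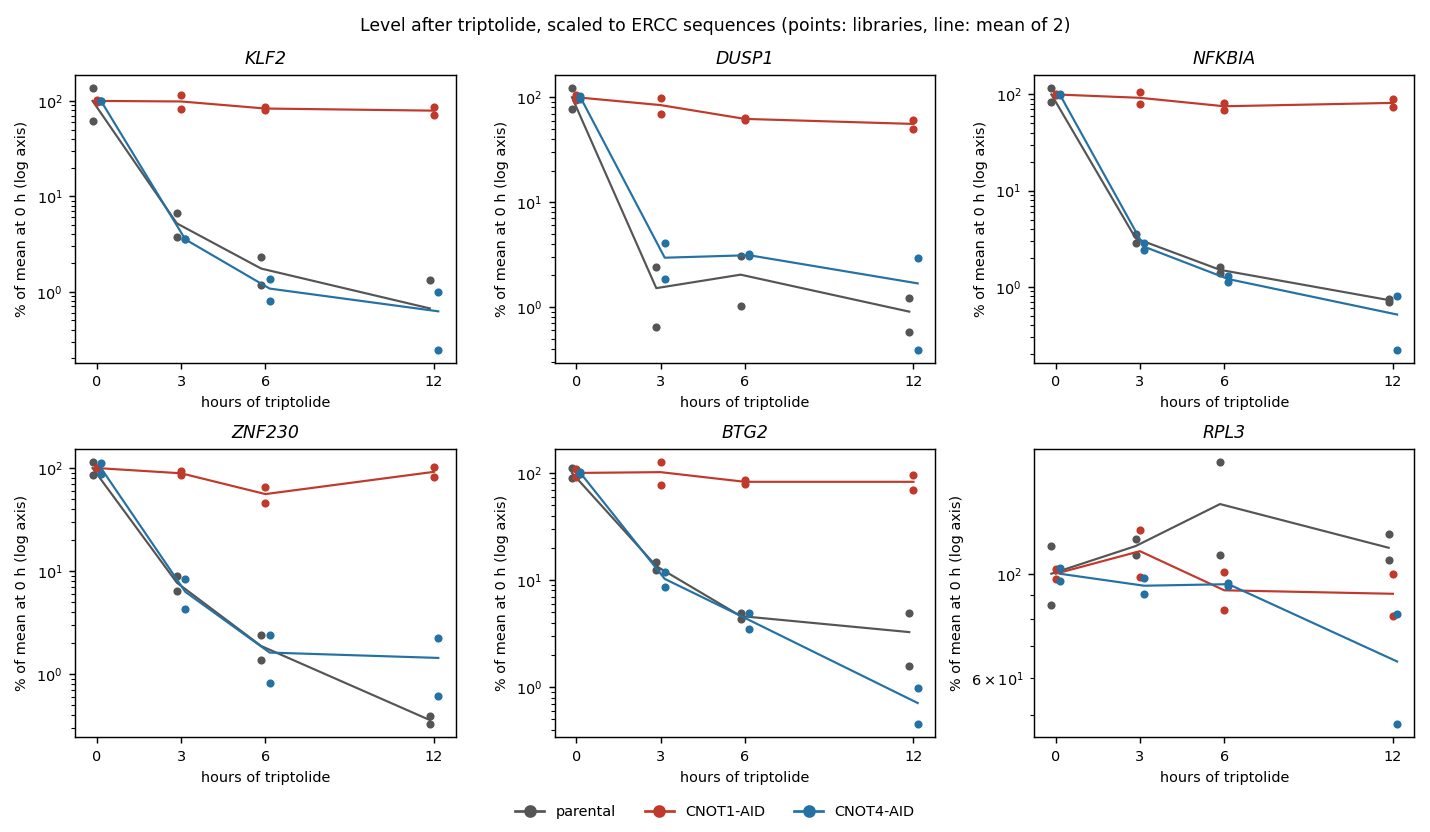
Level after triptolide as percent of the mean at 0 h (log axis), scaled to ERCC sequences, for 6 genes in 3 lines over 0, 3, 6 and 12 h (points are libraries, lines the mean of 2). At 12 h BTG2 stood at 82.6% in CNOT1-AID, 3.27% in parental and 0.711% in CNOT4-AID cells.

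Among lists, immediate early genes slowed most often: 37 of 51 (42 adjusted over the list alone), with CYR61 (0.55) and the stress genes DDIT4 (0.58) and DDIT3 (0.53) alongside. Of 367 zinc finger genes 202 slowed (246 adjusted over the list alone), led by ZNF416 (0.69), ZNF223 (0.58) and ZNF7 (0.49). Of 53 G2/M genes 22 slowed (26 adjusted over the list alone), among them CKS2 (0.34 ± 0.035), HJURP (0.31) and PLK1 (0.30), with E2F8 (0.34) and CCNE1 (0.22) of the G1/S list. Of 26 p53 targets 13 slowed (13 adjusted over the list alone), SESN2 by 0.46. These lists passed camera with the preset correlation, and no list passed for slopes with an estimated correlation in camera (immediate early genes 1.51e-18 preset, adjusted p = 0.89 with an estimated correlation). BTG2 (0.46), BTG1 (0.39), TOB1 (0.33), ZFP36L2 (0.34), PELO (0.40), SMG8 (0.37), EPHB3 (0.45), SP5 (0.42), AXIN2 (0.39), SOX9 (0.37), ANKRD1 (0.45), CTGF (0.44), DNAJB1 (0.44), MCL1 (0.34) and TIPARP (0.50) also slowed, as did the subunits CNOT8 (0.20), CNOT2 (0.17), CNOT4 (0.14) and CNOT6L (0.12). GDF15 (0.38), PLK2 (0.37), IRF1 (0.37), DDIT4 and DDIT3 lost their calls without parental 0 h replicate 1 (adjusted p = 0.0978, 0.0588, 0.109, 0.083 and 0.051). The calls of GDF15, PLK2, IRF1 and DDIT4 also ended without CNOT1-AID 12 h replicate 1 (0.0832, 0.0696, 0.112 and 0.0679). Those of IRF1 and DDIT4 ended without CNOT1-AID 12 h replicate 2 (0.0555 and 0.0509) and GDF15 without CNOT1-AID 0 h replicate 1 (0.0513). The 78 ribosomal protein mRNAs had a median slope difference of -0.04, with RPS2 at -0.03 ± 0.033 and RPLP0 at -0.03 ± 0.030, and 0 of them passed with ERCC scaling. With TMM scaling 76 passed as faster, and with ribosomal protein scaling 3 passed as faster and 12 as slower. EEF1A1 (-0.02 ± 0.031) passed as faster with TMM scaling.

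The median half-life of 9369 genes was 13 h in parental cells (quartiles 6.69 and 28.4 h), 33.3 h in CNOT1-AID cells (21.5 and 52 h) and 6.33 h in CNOT4-AID cells (4.14 and 9.19 h). It was 58.5 h and 19.6 h in CNOT1-AID replicates 1 and 2 alone, and 7.17 h and 4.91 h in CNOT4-AID replicates 1 and 2 alone. The last sample was at 12 h, so the CNOT1-AID values, like long half-lives of single genes, are extrapolated and rough. With ribosomal protein scaling the medians in parental, CNOT1-AID and CNOT4-AID cells were 9.97, 54.8 and 9.35 h over 8296 genes. With TMM they were 12.5, 39.4 and 10.2 h over 2320 genes, since each scaling keeps the genes that decline in all 3 lines under it. Times under these scalings are relative to ribosomal protein mRNAs or to the bulk of genes, so they are not absolute. Slowing was largest for genes that were short-lived in parental cells: a median of 0.23 log2 per hour for 950 genes with a half-life under 4 h. It was 0.09 for 1984 genes at 4 to 8 h, 0.01 for 2492 genes at 8 to 16 h and -0.03 for 4815 genes that had a half-life over 16 h or did not decline in parental cells. Of 2714 slowed genes in both sets 2185 also rose at 8 h of auxin (940 by chance) and 2138 at 24 h (1033.7 by chance), such as KLF2, NFKBIA and BTG2. Across 14102 genes the slope difference and the steady-state response had r of 0.51 and rho of 0.56 at 8 h, and r of 0.45 and rho of 0.50 at 24 h, genes not being independent replicates. In CNOT4-AID cells r was -0.02 and 0.01.

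In CNOT4-AID cells slopes were compared with parental cells as well, and calls depended on the scaling. The nucleolar gene NOP16 (chromosome 5) went from a half-life of 3.07 h to 1.86 h (-0.21 ± 0.042, adjusted p = 0.0169). RMRP (-0.27), RNVU1-7 (-0.25), ZNF708 (-0.22), SCARNA16 (-0.22), NCBP2-AS2 (-0.21), ZNF607 (-0.21), ZNF274 (-0.20), MRFAP1L1 (-0.20) and the pseudogene RPL14P1 (-0.22, shared reads possible) also had lower slopes. Of these RMRP, RNVU1-7, SCARNA16 and RPL14P1 rose after triptolide in parental cells (0.206, 0.182, 0.117 and 0.163) and declined in CNOT4-AID cells (-0.068, -0.065, -0.101 and -0.052). ZNF708 and ZNF607 were already lower in untreated CNOT4-AID than in parental cells (log2 -2.54 and -2.67). Their mean of at least 5 CPM is taken over both lines and can come from parental cells, so their CNOT4-AID slopes may rest on low counts. CENPF (-0.16), CKS2 (-0.15) and CENPA (-0.14) of the G2/M list (11 of 53 faster; 43 adjusted over the list alone), JUND (-0.14), TRIB3 (-0.13), CTCF (-0.14) and CNOT8 (-0.12, adjusted p = 0.0488) passed too, and 39 of 367 zinc finger genes (154 adjusted over the list alone). The median of all genes was -0.08 with ERCC scaling and -0.004 with TMM and with ribosomal protein scaling. TMM levels most genes between libraries, so its median lies near 0 by construction. Ribosomal protein scaling removes any loss that other genes share with those mRNAs. With TMM and with ribosomal protein scaling the calls of the genes named here ended, except MRFAP1L1 with TMM. With each, 1 of the 367 zinc finger genes passed as faster. Altogether edgeR called 516 genes, 515 faster and 1 slower (8258 at unadjusted p under 0.05). The count was 0 without CNOT4-AID 12 h replicate 2, where NOP16 stood at -0.17 (adjusted p = 0.207), and 10234 without its partner. Without other CNOT4-AID libraries it was 12 and 50 (0 h), 78 (3 h replicate 2), 49 and 102 (6 h), and without parental libraries 2912 and 39 (0 h), 39 and 20 (3 h), 3435 (6 h replicate 2), 4 and 5210 (12 h). The long-lived GAPDH had 108%, 96.2% and 60% of its 0 h level left at 12 h in parental, CNOT1-AID and CNOT4-AID cells, and ACTB 97.4%, 93.2% and 54.8%.

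CNOT1-AID and CNOT4-AID slopes were compared last. BAMBI (0.98 ± 0.11), CHAC1 (0.93 ± 0.16) and the chaperone partner FKBPL (0.86 ± 0.085), with a half-life of 45.7 h without CNOT1 and 1.14 h without CNOT4, lasted longer without CNOT1, while RF00003 (-0.17) and HIST1H4C (-0.09) lasted longer without CNOT4. The last 2 lost their calls without single libraries, for example without CNOT4-AID 12 h replicate 1 (adjusted p = 0.114 and 0.119). In all 7856 genes differed, 7823 slower without CNOT1 and 33 faster (3866 and 2812 with TMM scaling).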

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

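The test of the CNOT4-AID library with a high ERCC share and the test of ERCC scaling were chosen after their results were seen, as were the half-lives without single libraries, the overlap of slowed and raised genes, and r between untreated differences with no library in common over all genes; the other tests in this part were set before.

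Responses that differed between groups were marked by tests of the difference itself. Against parental cells 7504 genes at 8 h and 9237 at 24 h differed without CNOT1, among them ZNF296, DUSP2, TXNIP and TSPAN8, and 2 loci at 8 h and 10 at 24 h differed without CNOT4, among them SMIM19, UTP23, METTL5 and DHCR7. CNOT1-AID and CNOT4-AID responses differed for 7704 genes at 8 h and 9278 at 24 h, such as IER5L, GPRC5C and CXCL5. Responses at 24 h and 8 h differed for 5422 genes without CNOT1, such as IER3, PSMB9 and ASCL2, and for 3 without CNOT4, such as B3GNT3. Slopes of mRNA loss differed from parental cells for 2935 genes in CNOT1-AID cells (KLF2, NFKBIA, BTG2) and 516 in CNOT4-AID cells (NOP16, CENPF). Between the tagged lines they differed for 7856 (BAMBI, CHAC1, FKBPL).

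Faster loss of mRNAs such as NOP16 and CENPF in CNOT4-AID cells depends on single libraries and on the scaling. Without CNOT4-AID 12 h replicate 2, the library with the highest ERCC share (3.92%, against 2.25% in its partner), the count of called genes went from 516 to 0 in edgeR. The fall is not specific to that library: the count was 4 without parental 12 h replicate 1, 12 and 50 without CNOT4-AID 0 h replicates 1 and 2, 39 without parental 0 h replicate 2, 39 and 20 without parental 3 h replicates 1 and 2, 78 without CNOT4-AID 3 h replicate 2, and 49 and 102 without CNOT4-AID 6 h replicates 1 and 2. It rose to 2912, 3435, 5210 and 10234 without parental 0 h replicate 1, parental 6 h replicate 2, parental 12 h replicate 2 and CNOT4-AID 12 h replicate 1, and DESeq2 called 5993 with all libraries. The slopes moved less than the calls: without the library with the highest ERCC share the median slope difference was -0.05, against -0.08 with it, and NOP16 stood at -0.17 against -0.21. With scaling to ribosomal protein mRNAs the median slope difference was -0.004. The median half-life in CNOT4-AID and parental cells was 6.33 and 13 h with ERCC scaling (7.8 h in CNOT4-AID cells without that library), 9.35 and 9.97 h with ribosomal protein scaling, and 10.2 and 12.5 h with TMM. These rest on 9369, 8296 and 2320 genes, those that decline in all 3 lines under each scaling, so part of the difference may lie in the genes. Ribosomal protein scaling and TMM also remove a loss shared with ribosomal protein mRNAs or with most genes. They therefore do not test a loss shared by all mRNAs. A greater loss of total mRNA after triptolide in CNOT4-AID cells could also raise the ERCC share. At 12 h protein-coding genes took 85.48% and 84% of counts in CNOT4-AID and 85.88% and 82.58% in parental cells. Small nuclear RNAs took 1.592% and 1.56% against 1.877% and 2.64%, and mitochondrial genes 6.128% and 5.565% against 4.822% and 4.436%. Within the CNOT4-AID pair these shares were close, while the ERCC shares were not. They are relative to other RNA, and only ERCC sequences were added in a fixed amount, so these data leave the question open. Of 60 splits of the CNOT4-AID and parental libraries within time 6 gave at least the real 516 genes, the highest other 2786, so chance cannot be excluded from them. What lets some splits reach such counts was not tested, and the median of the other splits was 0 genes. These splits mix lines that differ in level for 2012 genes at 0 h, and so are not a case without change.

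Zinc finger genes of chromosome 19, among them ZNF540, ZFP30 and ZNF571, were lower in both untreated tagged lines. The shared parental libraries are argued against, because over these genes the CNOT1-AID difference at 8 h and the CNOT4-AID difference at 24 h, which share no library, had r of 0.932 (across 176 genes, which are not independent). Loss of chromosome segments, as a candidate explanation, meets the bound set before. The 23 other genes inside the affected clusters, which lie apart between 21020620 and 56588911, had a median of -1.188 in CNOT1-AID cells (quartiles -1.728 and -0.762). In CNOT4-AID cells it was -1.114. Between 51804816 and 53458261 the medians of the other genes were -0.751 and -0.69. Many of the 23 are pseudogenes or non-coding loci, such as VN1R82P and LINC01534, so they are a weak probe of segment loss. Only 11 of the 27 zinc finger genes between 51804816 and 53458261 were affected, and DNA was not measured, so that silencing of these clusters in an ancestor of both lines may explain the same values. For the untreated differences as a whole, the real split of 8 libraries gave 2757 and 2522 genes in CNOT1-AID and CNOT4-AID cells. The other 34 splits gave at most 446 and 396, so only 1 of 35 splits reached the real count in each, the smallest share possible here. Splits that mix the lines also add the line difference to the spread, which lowers their counts, so they cannot exclude chance.

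Slowing in CNOT1-AID cells was greatest for mRNAs that were short-lived in parental cells, such as KLF2 and MYC. Every triptolide library had auxin, so line and removal of CNOT1 cannot be told apart in these slopes. Across genes, which are not independent replicates, the parental slope in replicate 1 and the slope difference in replicate 2 had rho of -0.67, and -0.753 with the replicates exchanged, so that noise shared between the values is argued against; a loss of decay in proportion to its normal rate may produce this trend. GC content at codon position 3 had rho of -0.281 in replicate 2 and 0.199 in replicate 1, and the opposite signs keep its role open. Over all libraries its rho was -0.035, and with the CNOT1-AID auxin response it was -0.127 at 8 h and -0.082 at 24 h. Of 60 splits of the libraries within time, 11 gave at least the real 2935 genes for CNOT1-AID and parental cells (highest other 6466) and 15 at least the real 7856 for the tagged lines (highest other 10743). The median of the other splits was 0 genes in each comparison. Chance cannot be excluded from these splits, which mix lines that differ in level (2436 genes at 0 h between CNOT1-AID and parental cells) and so are not a case without change. Separate libraries argue against chance for the slowing without CNOT1: of 2714 slowed genes 2185 also rose at 8 h of auxin in the steady-state set, against 940 by chance, and r between slope difference and response was 0.514 (across 14102 genes, which are not independent replicates). For the tagged lines against each other no such test was run.

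Lower CNOT1 mRNA in untreated CNOT1-AID cells raised the question of an early partial loss. Across genes, which are not independent, the untreated difference at 8 h had r of -0.149 with the CNOT1-AID auxin response at 24 h, and the untreated CNOT4-AID difference had r of -0.022, so neither untreated difference resembled the response to CNOT1 loss. This does not test for a difference shared by the tagged clones, and other values point to one: the untreated CNOT1-AID and CNOT4-AID differences had r of 0.333 and 0.296 with no library in common.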

How the results depend on the processing

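Pseudocounts, TPM without scaling, protein-coding genes only, ERCC scaling at 0 h and half-lives without single libraries were chosen after seeing the data; the other alternatives were set before. Over 38 results 308 of 451 values stayed within 1.5 times or their spread and 143 moved. For median half-lives the spread was the SD of the values of replicates 1 and 2 alone, which were scored as alternatives too. In CNOT1-AID cells these were 58.5 and 19.6 h, so that 16.8 h and 54.8 h counted as unmoved against 33.3 h. Of 8503 values for named genes 7548 kept direction and side of the threshold, 864 lost the call, 81 gained it and 10 reversed. ZNF296, TXNIP, TSPAN8 and CXCL5 kept theirs in CNOT1-AID cells under each alternative. The cause was not tested unless given. DESeq2 on the steady-state set was not run. Depth of the TPM set is unknown.

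Requiring at least 2-fold in place of any size gave 2159 and 3848 genes in CNOT1-AID cells at 8 h and 24 h, 3 and 6 in CNOT4-AID cells, 2158 and 3859 for CNOT1-AID against parental cells, 1 for CNOT4-AID against parental cells at 24 h, 2197 and 3916 for CNOT1-AID against CNOT4-AID, 761 for 24 h against 8 h without CNOT1, and 135 and 171 for untreated CNOT1-AID and CNOT4-AID cells, since fewer genes can pass.

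ERCC scaling gave 1 gene in parental cells at 8 h, 5 and 1742 in CNOT4-AID cells, 1 for CNOT4-AID against parental cells at 24 h, 3306 for 24 h against 8 h without CNOT1, 1256 and 1871 in untreated CNOT1-AID and CNOT4-AID cells, and 1300 and 656 at 0 h of triptolide. No scaling gave 11 and 21 genes in CNOT4-AID cells, 2 against parental cells at 24 h, and 1719 and 8682 in untreated CNOT1-AID and CNOT4-AID cells. With ERCC scaling CNOT6 (0.16) and CNOT7 (0.18) reversed in CNOT1-AID cells at 8 h and CNOT11 (0.32) and CNOT10 (0.34) at 24 h; without scaling CNOT7 (0.003) at 8 h, CNOT11 (0.23) and CNOT10 (0.25) at 24 h, and CNOT8 (-0.19) and CNOT7 (-0.23) in untreated CNOT4-AID cells reversed.

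No filter gave 18 and 14 genes in parental cells at 8 h and 24 h, 249 in CNOT4-AID cells at 24 h, 22 against parental cells at 8 h, 14 for 24 h against 8 h without CNOT4, and 836 for CNOT4-AID slopes. A mean of at least 1 TPM gave 1 for CNOT4-AID against parental cells at 8 h and 0 for 24 h against 8 h (1381 at unadjusted p under 0.05 in limma's first fit), and protein-coding genes alone gave 0 in both (1061 for the former). Pseudocounts of 0.1 and 1 gave 2 genes each in parental cells at 24 h, and 0.1 gave 1 for CNOT4-AID against parental cells at 8 h.

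Only the libraries compared gave 11 and 4 genes in parental cells, 2 and 15 in CNOT4-AID cells, 5 and 3 against parental cells, 7 for 24 h against 8 h without CNOT4, 1463 in untreated CNOT1-AID cells, 19 for CNOT4-AID slopes, and 91 and 109 at 0 h, with fewer residual degrees of freedom. A replicate block, though the numbers showed no pairing of samples (median r 0.000472 and 0.00122), gave 5 for CNOT4-AID against parental cells at 24 h and 51 for CNOT4-AID slopes; a block within line and time gave 1 in parental cells at 8 h, 4 and 88 in CNOT4-AID cells, 1 against parental cells at 24 h and 1 for 24 h against 8 h without CNOT4.

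Slopes with TMM scaling gave 6091 genes (CNOT1-AID) and 16 (CNOT4-AID), with ribosomal protein scaling 7989 and 6, with 0, 3 and 6 h alone 796 and 0, and with 0 h and 3 h alone 630 and 0, where SCARNA16 reversed in CNOT4-AID cells (0.13); edgeR's first fit had 8258 CNOT4-AID genes at unadjusted p under 0.05, and DESeq2 gave 5993. CNOT1-AID against CNOT4-AID gave 2270 and 2037 with the shorter courses. The median half-life in parental, CNOT1-AID and CNOT4-AID cells, in this order, was 13, 33.3 and 6.33 h with ERCC scaling (9369 genes), 9.97, 54.8 and 9.35 h with ribosomal protein scaling (8296 genes), and 12.5, 39.4 and 10.2 h with TMM (2320 genes). It was 10.3, 16.8 and 4.64 h with 0, 3 and 6 h (5759 genes), 4.83, 16.9 and 2.87 h with 0 h and 3 h (2630 genes), 10.8, 58.5 and 7.17 h in replicate 1 alone (6770 genes), and 12.7, 19.6 and 4.91 h in replicate 2 alone (8907 genes). The genes differ between settings, since each keeps those that decline in all 3 lines. With ribosomal protein scaling or TMM the times are relative to those mRNAs or to the bulk of genes.

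Leaving out 1 library, with a lone library assumed to vary like the other groups, gave 1 to 2 genes in parental cells at 8 h and 0 to 5 at 24 h, 6 to 107 and 21 to 639 in CNOT4-AID cells, 2 to 10 and 1 to 46 against parental cells, 2 to 9 for 24 h against 8 h without CNOT4, 1903 to 3080 in untreated CNOT4-AID cells, 0 to 10234 for CNOT4-AID slopes, and 1156 to 6439 and 1353 to 6153 at 0 h; the libraries are named in the report.

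Across genes with a mean of at least 5 CPM in both sets, r of slope with response was 0.658 and 0.58 without CNOT1 and -0.058 without CNOT4 at 8 h, and 0.441 with TMM in both at 24 h; genes are not independent replicates. Subtracting the parental response gave r of 0.236 and 0.188 between the CNOT1-AID and CNOT4-AID responses, where shared parental libraries alone gave 0.475 and 0.527 in simulated data. The covariances were 0.071 and 0.0812, close to the simulated 0.0675 and 0.0763. With an estimated correlation camera called 0 and 1 lists in parental, 1 and 3 in CNOT1-AID and 1 and 2 in CNOT4-AID cells and 0 and 0 for slopes, against 10, 8, 10, 15, 8, 10, 15 and 8 with the preset; fry called 0, 1, 23, 24 and 4 for the first 5 and 25 for CNOT4-AID slopes.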

Other observations

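The comparison in this part, with its simulated and divided parental libraries, was not in the plan and was added after the data were seen. With ERCC scaling, slopes against parental cells were higher without CNOT1 and lower without CNOT4 for 301 genes (84.8 for independent lists), and lower in both for 27 (5.1 for independent lists). The 515 genes with lower slopes without CNOT4, from which these come, were 15 with TMM and 5 with ribosomal protein scaling, and 0 without CNOT4-AID 12 h replicate 2 in edgeR (8258 genes had an unadjusted p under 0.05 with all libraries). Without each other library of the comparison in turn the CNOT4-AID count was 4 to 10234. Across 16806 genes, which are not independent replicates, the 2 slope differences had r of 0.27. Both subtract the same parental libraries, which alone gave r of 0.474 to 0.526 in simulated data, and with the parental replicates divided between them r was -0.018. By rank, rho was 0.027, against 0.452 to 0.464 in simulated data, and -0.18 with the parental replicates divided. The covariance was 0.00253, within the 0.00244 to 0.00284 of the simulated data. The lower r therefore does not show that the lines act less alike than shared libraries predict. Whether the negative rho with divided replicates marks opposed changes was not tested.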
